A study of Homo sapiens with 3 samples.

How the data were processed

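Total RNA was extracted with Trizol from untreated HEK293T cells, captured on oligo-dT and made into directional libraries, per the labels' protocols, and 3 libraries labelled as biological replicates 1, 2 and 3 were used. Transcripts were quantified with kallisto against hg38, per the submitters' processing notes. The kallisto version, its options, the strand setting and the transcript release were not given in the sources used here. The deposited table gave, per transcript, TPM for each replicate, scaled by the authors within each library. It also gave the authors' mean TPM, the transcript length, kallisto's effective length and a column of estimated counts, per the file headers. The deposited estimated counts named no library: divided by effective length and rescaled, they equalled the TPM of replicate 1 within a relative difference of 1.08e-05, and they summed to 33184885. Per-library counts were therefore not used, the count model planned for tables with counts was replaced by the version planned for TPM, and the authors' mean TPM equalled the mean of the 3 columns within 3.33e-07.

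TPM was summed over the transcripts of each gene symbol, giving 35880 symbols. Transcript identifiers were matched to GENCODE release 29 on hg38 for gene types, positions and sequence: 90.4% of transcripts matched by identifier, 99.6% of those had the same length, and matched transcripts held 96.9% of the TPM of replicate 1. That release may not be the one the authors used. TPM keeps no depth, so depth was estimated from the spacing of low values: in transcripts longer than 1000 bases, TPM times effective length falls on multiples of what 1 read is worth. The best spacing gave 33100000, 33600000 and 33500000 reads for replicates 1, 2 and 3, where 26.0%, 25.7% and 26.9% of low values lay within 0.02 reads of a whole number against 4% by chance. These are estimates, and the first is close to the total of the estimated count column. Reads per gene were estimated as TPM times effective length times that depth, and rounded to whole numbers for edgeR. The single column of effective lengths, which goes with replicate 1, was used for all replicates. Any difference in effective length between libraries would add to the spread of estimated reads.

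Levels were tested with limma's moderated one-sample test of log2(TPM + 0.01) against 1 TPM, with a mean-variance trend and Benjamini-Hochberg adjustment over genes above 0 in at least 1 library. A gene with adjusted p under 0.05 was called above or below by its sign, other genes were undecided, and genes at 0 in all 3 libraries stood apart. Differences are on the log2(TPM + pseudocount) scale, which understates those of low genes. In each of 30 gene lists (23 pathways and 7 sets of cell type markers) members were counted per call, and the share above 1 TPM was set against all other symbols by Fisher's exact test. Partner pairs were tested with limma on the per-library difference of log2(TPM + 0.1), adjusted over 40 pairs. Replicate spread was described by correlations, CVs and an F-test of each gene's variance against limma's trended prior, over genes of mean TPM of at least 1. The read-based test compared the chi-square of estimated reads with sampling noise plus a common spread, over genes with at least 20 estimated reads. The main transcript was the most abundant one in each library, for genes with at least 5 TPM and more than 1 transcript. Sequence shared between genes was measured as the percent of 31-base words of a gene's transcripts found in transcripts of another symbol. Words were taken from the transcript strand only, and only from transcripts matched to the annotation.

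The tests, gene lists, pairs, and most alternatives were fixed before the data were examined. The genes named in the text were the 20 with the highest mean TPM, members of the fixed lists and pairs with at least the highest or lowest of each list (some members are not reported here), the 10 with the largest excess spread past the threshold (0 passed), and for main transcripts the 5 most abundant genes with and the 5 without the same transcript in every library. Genes named from the read-based test, and the gene families in the closing part, were chosen after their values were seen. Added after the data were seen were a quasi-likelihood F-test built on edgeR's fit to estimated reads (called edgeR on estimated reads), the read-based spread test and the protein-coding background. The F was the deviance at 1 TPM minus the fitted deviance, over edgeR's moderated quasi-dispersion. It was formed separately because edgeR's own F-test does not take a design of 1 column. Also tried, and fixed in advance, were other pseudocounts, levels of 0.5 and 2 TPM, TMM and median-of-ratios scaling, filters on mean TPM, rescaling without mitochondrially encoded genes and leaving out each replicate.

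The methods were tested on data simulated from the real mean TPM, effective lengths and estimated depths of the 35880 symbols. Every gene got sampling noise and the same added spread of 1.3%, and no reads were shared between genes or transcripts. The real data are noisier: between 1 and 5 TPM the median CV was 13.9%, where sampling alone gave 8.61%. The rates below may therefore be too favourable. The level test called 100% of genes set at 0.5 TPM and 97.1% of those set at 2 TPM on the right side, and it called 2% of genes set at 1 TPM. The pair test called 100% of 40 pairs set at a ratio of 1.2 and left 97.5% of equal pairs uncalled. The planned excess-spread test recovered 0% of genes given an extra SD of 0.2, and the read-based test recovered 82% of them and called 0.0435% of unchanged genes. Near-identical genes, overlapping genes and antisense genes share reads or words, so their TPM is uncertain, and oligo-dT capture lowers RNAs without a poly(A) tail. Calculations used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1 and edgeR 4.0.16. With 3 samples in 1 group no comparison between groups was possible.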

Results

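HEK293T is an established human embryonic kidney cell line that carries the SV40 large T antigen and is widely used for transfection and protein production. Untreated cells were cultured in high-glucose medium containing 10% fetal bovine serum and collected at 70% confluence, and RNA captured on oligo-dT was sequenced from 3 libraries labelled as biological replicates. The 3 libraries formed 1 group, so each gene's level was compared with 1 TPM (the transcripts-per-million unit), partner genes were compared within libraries, and the libraries were compared with each other. Abundance was given for 185299 transcripts of 35880 gene symbols. Depth, estimated from the spacing of the lowest values, was about 33100000, 33600000 and 33500000 reads in replicates 1, 2 and 3, so 1 TPM over 2000 effective bases stood for about 47.4, 48.2 and 48.0 reads. Levels are mean TPM ± SD over the 3 libraries (n = 3). The labels do not say whether the replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

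Transcripts of the mitochondrial genome and of ribosomal protein genes were the most abundant. The 13 mitochondrially encoded protein genes held 6.62% ± 0.141 of the TPM, and 87 ribosomal protein genes held 20.6% ± 0.0579 (SD, n = 3). The highest TPM was listed for MT-ATP8, which encodes a subunit of the mitochondrial ATP synthase, at 10098 ± 437 TPM. It was followed by the cytochrome c oxidase subunits MT-CO2 (7854 ± 174 TPM) and MT-CO3 (7727 ± 151 TPM) and by the ATP synthase subunit MT-ATP6 (7521 ± 203 TPM). The short MT-ATP8 entry (8366 to 8572 of the mitochondrial genome) overlaps MT-ATP6 (8527 to 9207) at 1 end only. Of the 31-base words of MT-ATP8, 44.6% occur in another gene, most of them outside that overlap. Its rank above MT-ATP6 is therefore uncertain. EEF1A1, which delivers aminoacyl-tRNA to the ribosome, was listed at 6779.9 ± 83.8 TPM, RPL41 at 6101 ± 34.8 TPM and RPS2 at 5989 ± 24.3 TPM. Among the 20 most abundant genes, 7 were mitochondrially encoded, 10 encoded ribosomal proteins, and the other 3 were EEF1A1, the nucleolar protein gene NPM1 (4957 ± 31.5 TPM) and the ribosome-associated scaffold gene RACK1 (3756 ± 23.8 TPM). Also in the top 20 were MT-CO1 at 6757 ± 89.2 TPM, MT-ND4L, MT-ND3, RPL39, RPL37A, RPL4, RPL10, RPL36A, RPS27 and RPS18. The 10 most abundant genes held 6.98% ± 0.0982 of all TPM, the top 100 held 31.5% ± 0.144, and the top 1000 held 63.5% ± 0.144.

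Of the 19849 protein-coding gene symbols, 12200 (61.5%) lay above 1 TPM, 4098 lay below it, 966 could not be placed on either side, and 2585 were listed at 0 in all 3 libraries. Pseudogenes were mostly low: 571 of 14694 lay above 1 TPM and 10314 were listed at 0. Over all 35880 symbols, 12856 lay above, 7454 below and 1680 undecided by limma's moderated one-sample test of log2(TPM + 0.01) with Benjamini-Hochberg adjustment, and 13890 were listed at 0. A value of 0 is reported as listed at 0, since quantification can set a transcript to 0 by assigning its reads to a relative. Each fixed gene list was compared with all other genes by Fisher's exact test (two-sided, 30 lists), against a share of 35.8% of all symbols above 1 TPM, and also with protein-coding genes alone, a background chosen after the data were seen. The first background holds the mostly low pseudogenes, so lists of coding genes pass against it more easily. Lists with every member above 1 TPM also passed against coding genes, but with larger Fisher adjusted p. These ran from 0.00491 for replication and mitosis to 0.0271 for the microRNA machinery. Genes are not independent replicates, so these tests describe the lists. Counts adjusted over the list alone were the same as those adjusted over all genes tested in each list except the cytidine deaminases.

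**Figure D1:**
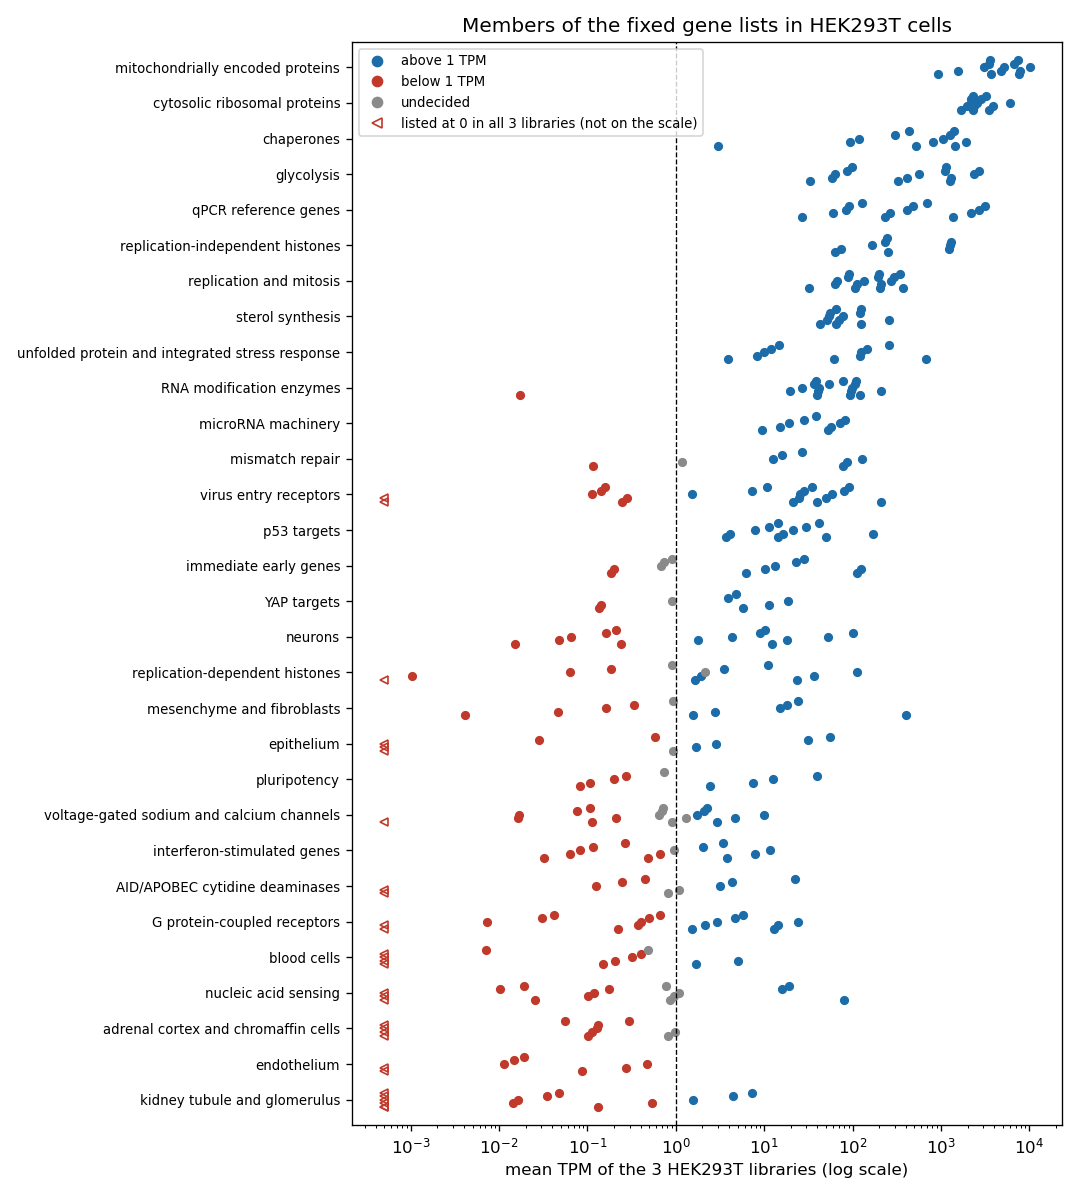
Mean TPM of the 3 HEK293T libraries (log scale, 1 point per gene) for each fixed gene list, ordered by its median, with the level of 1 TPM as a dashed line. Open triangles mark genes listed at 0 in all 3 libraries, which have no place on the log scale, and colours give the limma call. All 13 ribosomal protein genes and all 14 glycolytic genes lie above 1 TPM, and none of the 8 endothelial markers does.

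Housekeeping genes were above 1 TPM without exception in 5 fixed lists. All 13 cytosolic ribosomal protein genes passed, from RPS27A at 1675 ± 27.97 TPM to RPS2, and so did all 13 mitochondrially encoded genes, from MT-ND6 (918 ± 87.9 TPM) to MT-ATP8 (adjusted p = 7.99e-06 for each list). All 14 glycolytic genes lay above 1 TPM (adjusted p = 5.72e-06). GAPDH was highest at 2689.5 ± 21.6 TPM, the enolase ENO1 stood at 2376 ± 27.3 TPM, the terminal enzymes PKM and LDHA at 1131 ± 12.8 TPM and 1104 ± 26.3 TPM, and the hexokinase HK2 was lowest at 32.7 ± 0.951 TPM. The 12 chaperone genes were all above 1 TPM (adjusted p = 1.49e-05), led by the constitutive HSP70 gene HSPA8 at 1903 ± 37.8 TPM. The stress-inducible copies HSPA1B (chromosome 6, 31827735 to 31830255, hg38) and HSPA1A (31815464 to 31817946) were listed at 1401 ± 50.9 TPM and 3.01 ± 0.447 TPM, but they are nearly identical in sequence and the split between them is uncertain. Among 14 genes used as qPCR references, all were above 1 TPM (adjusted p = 5.72e-06), from the TATA-binding protein gene TBP at 26.5 ± 1.46 TPM to the cyclophilin gene PPIA at 3110.3 ± 41.4 TPM, and their median coefficient of variation (CV) between libraries was 2.38%.

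Genes of DNA replication and mitosis were all expressed, as were p53 target genes, while mismatch repair was split. All 16 replication and mitosis genes lay above 1 TPM (adjusted p = 2.2e-06). The replicative helicase subunit MCM7 reached 374 ± 4.78 TPM, the sliding clamp PCNA 348 ± 1.29 TPM, the mitotic cyclin CCNB1 273 ± 3.86 TPM, and the G1/S cyclin CCNE1 was lowest at 32.00 ± 1.33 TPM. All 12 p53 targets were above 1 TPM (adjusted p = 1.49e-05), among them the pro-apoptotic BAX at 168 ± 6.81 TPM, the p53 ligase MDM2 at 50.02 ± 2.83 TPM, the CDK inhibitor CDKN1A at 14.2 ± 1.33 TPM and the death receptor FAS at 3.68 ± 0.595 TPM. Of 8 mismatch repair genes, 6 lay above 1 TPM, 1 below, and 1 was undecided, a share that did not pass the test against other genes (adjusted p = 0.0571). MSH6 was highest at 126 ± 1.11 TPM, PMS2 stood at 16.04 ± 0.516 TPM, and MLH3 was undecided at 1.18 ± 0.208 TPM. Without replicate 1 the list had 0 members below 1 TPM.

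Most sensors of foreign nucleic acid were low, although 3 genes that act downstream of them were above 1 TPM. Of 16 nucleic acid sensing genes, 3 lay above 1 TPM, 6 below, 4 were undecided, and TLR8, TLR9 and IFI16 were listed at 0. The 3 above were the transcription factor IRF3 at 79.3 ± 3.85 TPM, the kinase TBK1 at 18.98 ± 0.260 TPM and the mitochondrial adaptor MAVS at 15.8 ± 0.106 TPM. The cytosolic DNA sensor CGAS was listed at 0.101 ± 0.0170 TPM, the double-stranded RNA sensors IFIH1 and TLR3 at 0.175 ± 0.0338 TPM and 0.120 ± 0.0166 TPM, and IRF7 at 0.0306, 0 and 0 TPM in replicates 1, 2 and 3, all called below 1 TPM. The STING gene, TMEM173, and the RIG-I gene, DDX58, were undecided at 0.955 ± 0.134 TPM and 1.09 ± 0.0836 TPM. Among 13 interferon-stimulated genes, 5 lay above 1 TPM, 7 below and 1 was undecided. IFI6 was highest at 11.6 ± 0.768 TPM, the ubiquitin-like modifier ISG15 stood at 7.92 ± 0.294 TPM, and the oligoadenylate synthetase OAS1 was lowest at 0.0320 ± 0.0222 TPM. Of 10 AID/APOBEC cytidine deaminases, APOBEC3C (22.1 ± 0.187 TPM), APOBEC3B (4.32 ± 0.506 TPM) and APOBEC3F (3.19 ± 0.421 TPM) lay above 1 TPM, 3 lay below, 2 were undecided, and APOBEC1 and APOBEC2 were listed at 0. Adjusted over the list alone, 2 deaminases lay below and 3 were undecided, with APOBEC3H (0.448 ± 0.247 TPM) now undecided (adjusted p = 0.0443 over all genes and 0.0542 over the list). The call for APOBEC3H also ended without replicate 2 or replicate 3 (limma adjusted p = 0.0875 and 0.0803) and when TPM was rescaled without mitochondrially encoded genes (0.0552). The APOBEC3 genes resemble each other, so their split is uncertain. None of these 3 lists passed the test against all other genes (adjusted p = 0.295, 1 and 1), whereas against coding genes alone the sensing list held a lower share above 1 TPM (18.8% against 61.5%, adjusted p = 0.0075), and the other lists did not pass (adjusted p = 0.216 and 0.0826).

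Enzymes that modify RNA and the microRNA machinery were expressed almost throughout. Of 17 RNA modification genes, 16 lay above 1 TPM (adjusted p = 6.2e-06). The pseudouridine synthase DKC1 was highest at 209.7 ± 8.74 TPM, the adenosine deaminase ADAR stood at 122 ± 2.40 TPM, the m6A methyltransferase METTL3 at 77.4 ± 0.415 TPM and the demethylase FTO at 54.4 ± 3.08 TPM. ADARB2, an ADAR family member best known from brain, was the exception at 0.0171 ± 0.0106 TPM. All 9 microRNA pathway genes lay above 1 TPM (adjusted p = 0.000243), from the Argonaute gene AGO4 at 9.49 ± 0.478 TPM to the exporter XPO5 at 82.2 ± 0.834 TPM. The processing nucleases DROSHA and DICER1 stood at 71.6 ± 4.70 TPM and 38.5 ± 1.24 TPM.

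Surface receptors and channels were mixed. Of 21 virus entry receptors, 14 lay above 1 TPM, 5 below, and 2 were listed at 0, among them SLC10A1. The amino acid transporter SLC1A5, a retrovirus receptor, was highest at 211 ± 3.75 TPM, the transferrin receptor TFRC stood at 90.4 ± 3.09 TPM and the adenovirus receptor CXADR at 24.5 ± 0.840 TPM. The transmembrane serine protease TMPRSS2 lay below 1 TPM at 0.246 ± 0.175 TPM. The TMPRSS2 call was lost without replicate 1 (limma adjusted p = 0.0602). This list exceeded all other genes (66.7% against 35.8%, adjusted p = 0.0118) but not coding genes alone (adjusted p = 0.882). Of 18 voltage-gated sodium and calcium channel genes, 6 lay above, 6 below, 5 were undecided, and SCN10A was listed at 0. The T-type calcium channel gene CACNA1H was highest at 9.94 ± 1.05 TPM. The channel list did not pass against all genes (adjusted p = 1) and was lower than coding genes (33.3% against 61.5%, adjusted p = 0.0433). Of 18 G protein-coupled receptors, 8 lay above 1 TPM, led by the nucleotide receptor P2RY11 (24.4 ± 0.663 TPM), the thrombin receptor F2R (14.2 ± 0.509 TPM) and the adenosine receptor ADORA2B (12.99 ± 0.605 TPM). Another 8 lay below, including the mu opioid receptor OPRM1 at 0.224 ± 0.0629 TPM, and DRD1 and HTR1A were listed at 0 (adjusted p = 0.56 for the list).

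Sterol synthesis and stress response genes were all above 1 TPM, and immediate early genes were so in part. All 12 sterol synthesis genes passed (adjusted p = 1.49e-05), with the farnesyl diphosphate synthase FDPS highest at 257 ± 8.60 TPM. All 11 genes of the unfolded protein and integrated stress responses passed (adjusted p = 3.74e-05), led by the transcription factor ATF4 at 680.3 ± 8.38 TPM and the endoplasmic reticulum chaperone HSPA5 at 259 ± 4.35 TPM, with the glutathione-degrading CHAC1 lowest at 3.91 ± 0.589 TPM. Of 12 immediate early genes, 7 lay above 1 TPM, 2 below and 3 were undecided (adjusted p = 0.234). JUN and MYC were highest at 125 ± 3.47 TPM and 113 ± 1.86 TPM, whereas FOS and EGR1 were undecided at 0.682 ± 0.192 TPM and 0.728 ± 0.0813 TPM and EGR2 lay below at 0.186 ± 0.152 TPM. Without replicate 1 the EGR2 call was lost (limma adjusted p = 0.0611), which left 1 member below, and without replicate 3 FOS was called below (limma adjusted p = 0.038), which made 3. By edgeR on estimated reads 4 members lay below, FOS and EGR1 included. Of 8 YAP targets, 5 lay above, 2 below and 1 was undecided (adjusted p = 0.241). AMOTL1 was highest at 18.6 ± 0.176 TPM, CYR61 stood at 5.71 ± 0.142 TPM, CTGF was undecided at 0.902 ± 0.220 TPM, and ANKRD1 was lowest at 0.134 ± 0.0481 TPM.

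Replication-independent histone genes were abundant, and replication-dependent ones ranged widely. All 9 replication-independent histone genes lay above 1 TPM (adjusted p = 0.000243), with the variant genes H2AFZ at 1285 ± 18.1 TPM, H3F3A at 1266 ± 8.82 TPM and H3F3B at 1234 ± 24.5 TPM, and with H2AFY2 lowest at 63.5 ± 1.23 TPM. Of 13 replication-dependent histone genes, whose main transcripts end in a stem-loop without a poly(A) tail and are poorly captured by oligo-dT, 7 lay above, 3 below, 2 were undecided, and HIST1H1B was listed at 0 (adjusted p = 0.32). HIST1H2BK was highest at 111 ± 7.96 TPM and HIST1H4C stood at 36.3 ± 1.91 TPM, and reads of these multicopy genes can be shared between copies. The fixed list of 16 long non-coding RNAs was not analysed here.

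None of the lineage lists was above 1 TPM throughout. Of 9 pluripotency genes, 4 lay above 1 TPM, 4 below and 1 was undecided (adjusted p = 0.836). The let-7 repressor LIN28B was highest at 39.6 ± 0.465 TPM, the telomerase gene TERT stood at 12.7 ± 0.607 TPM and SOX2 at 7.41 ± 0.144 TPM, while POU5F1 and NANOG lay below at 0.197 ± 0.108 TPM and 0.0813 ± 0.0216 TPM. Among 14 neuronal markers, 8 lay above and 6 below (adjusted p = 0.253). The neurofilament genes NEFM and NEFL reached 99.97 ± 1.15 TPM and 52.7 ± 0.482 TPM, the intermediate filament gene INA 18.02 ± 0.812 TPM and the synaptic vesicle gene SYP 12.3 ± 0.376 TPM, while MAP2 lay below at 0.240 ± 0.0613 TPM and SNAP25 was listed at 0, 0.0451 and 0 TPM in replicates 1, 2 and 3. Of 15 kidney markers, the endocytic receptor LRP2 (7.24 ± 0.503 TPM) and the transcription factors WT1 (4.46 ± 0.565 TPM) and PAX2 (1.57 ± 0.0836 TPM) lay above 1 TPM, 6 lay below, and 6 were listed at 0, among them UMOD and AQP2 (adjusted p = 0.354). None of 12 adrenal markers lay above 1 TPM. Of these, 6 lay below, including the steroidogenic factor NR5A1 at 0.132 ± 0.0655 TPM, CHGA (0.987 ± 0.204 TPM) and PNMT (0.811 ± 0.381 TPM) were undecided, and 4 were listed at 0, among them TH and DBH (adjusted p = 0.0127).

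Markers of mesenchyme and epithelium were expressed in part, and those of blood and endothelium were mostly low. Of 11 mesenchymal markers, 6 lay above 1 TPM, 4 below and 1 was undecided (adjusted p = 0.31), with vimentin, VIM, at 401 ± 8.62 TPM, N-cadherin, CDH2, at 24.2 ± 0.440 TPM, the collagen gene COL1A1 at 18.1 ± 0.407 TPM, and THY1 lowest at 0, 0 and 0.0125 TPM in replicates 1, 2 and 3. Of 10 epithelial markers, KRT18 (55.2 ± 1.55 TPM), KRT8 (31.3 ± 1.43 TPM), E-cadherin, CDH1 (2.82 ± 0.868 TPM), and EPCAM (1.68 ± 0.165 TPM) lay above, 2 below, 1 was undecided, and KRT5, KRT7 and KRT19 were listed at 0 (adjusted p = 0.836). The epithelial genes below 1 TPM, 2 with all libraries (CLDN4 and KRT14), numbered 0 without replicate 1 and 1 without replicate 2, since CLDN4 was called in neither (limma adjusted p = 0.0927 and 0.105) and KRT14 was at 0 in replicates 2 and 3. Of 12 blood cell markers, 2 lay above, led by HBA1 (5.03 ± 0.786 TPM), 5 below, 1 was undecided, and 4 were listed at 0, among them HBB and CD3E (adjusted p = 0.317). The number of blood markers below 1 TPM was 3 without replicate 1, where PTPRC and SPI1 were no longer called (limma adjusted p = 0.0503 and 0.055). HBA1 and HBA2 are near copies, and HBA2 was listed at 0.383, 0 and 1.08 TPM in replicates 1, 2 and 3. None of 8 endothelial markers lay above 1 TPM, 6 lay below and ERG and CLDN5 were listed at 0 (adjusted p = 0.107). EMCN, the highest, was at 0.477 ± 0.166 TPM, and its call ended without replicate 1 or 3 (limma adjusted p = 0.0659 and 0.0677). Against coding genes alone, the kidney and blood lists (adjusted p = 0.00754 for each) and the endothelial list (adjusted p = 0.00491) held lower shares above 1 TPM, as did the adrenal list (adjusted p = 0.00032).

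Within libraries, 37 of 40 fixed partner pairs differed by limma on log2(TPM + 0.1) with Benjamini-Hochberg adjustment over the pairs, each in the same direction in 3 of 3 libraries, and the highest adjusted p among them was 0.00509 for the demethylases TET1 and TET2 (0.33 ± 0.05). Several paralog pairs lay far apart: MYC exceeded MYCN by 8.30 ± 0.19 on the log2 scale (SE, adjusted p = 4.72e-05), LIN28B exceeded LIN28A by 7.60 ± 0.13, the tubulin gene TUBB exceeded TUBB3 by 7.11 ± 0.02, and EEF1A1 exceeded EEF1A2 by 6.51 ± 0.02. The G1 kinase CDK4 exceeded CDK6 by 4.37 ± 0.02, the splicing repressor PTBP1 exceeded PTBP2 by 3.92 ± 0.06, the glucose transporter SLC2A1 exceeded SLC2A3 by 3.88 ± 0.07, and the maintenance DNA methyltransferase DNMT1 exceeded DNMT3A by 3.62 ± 0.03. In the opposite direction, the log2 ratio was -2.70 ± 0.07 for the exonucleases XRN1 and XRN2, -2.41 ± 0.02 for the cohesin subunits STAG1 and STAG2, -1.23 ± 0.02 for the actins ACTB and ACTG1, and -0.65 ± 0.03 for the lactate dehydrogenases LDHA and LDHB. VIM exceeded KRT18 by 2.86 ± 0.04 and CDH2 exceeded CDH1 by 3.10 ± 0.20. The deacetylases HDAC1 and HDAC2 (0.10 ± 0.03, adjusted p = 0.0522), the cyclins CCND1 and CCND2 (-0.05 ± 0.09, adjusted p = 0.575) and the histone genes H3F3B and H3F3A (-0.04 ± 0.02, adjusted p = 0.206) did not differ past the threshold. The HDAC1 and HDAC2 difference passed it with a pseudocount of 1 (adjusted p = 0.0422).

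**Figure D2:**
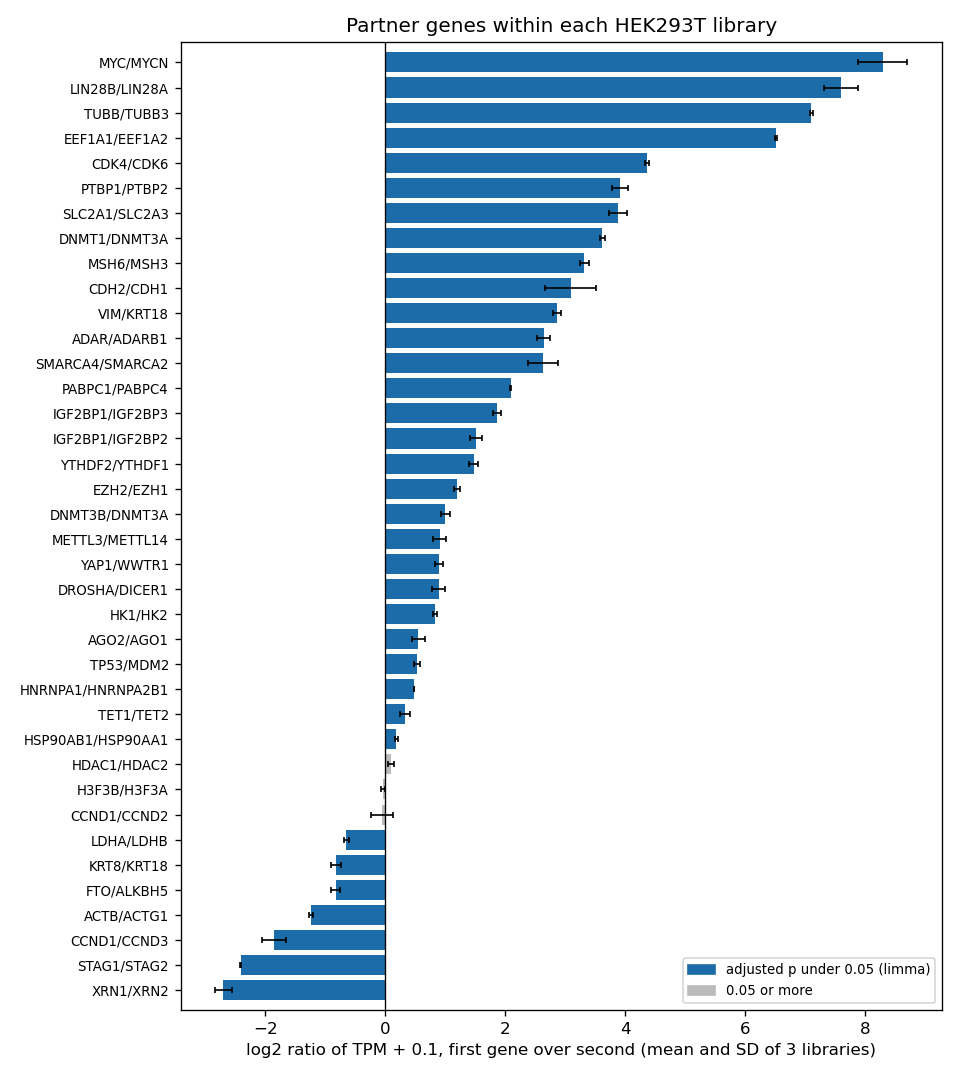
Mean log2 ratio of TPM + 0.1 (first gene over second) for 38 of the 40 fixed partner pairs in HEK293T, with error bars showing the SD of the 3 libraries. Blue bars had a limma adjusted p under 0.05 and grey bars did not, and the bars span from -2.70 for XRN1/XRN2 to 8.30 for MYC/MYCN.

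The 3 libraries were close to each other at every level of expression. Over 13475 genes of at least 1 TPM, Pearson's correlation of log2(TPM + 0.1) across genes was 0.985, 0.984 and 0.986 for replicates 1 and 2, 1 and 3, and 2 and 3, and Spearman's was 0.995 for each, where genes are not independent replicates. The median CV was 4.54% over all these genes, 13.9% for the 2781 genes between 1 and 5 TPM and 1.15% for the 142 genes above 1000 TPM. In reads estimated from TPM, effective length and depth, the median CV was 1.03% above 1000 TPM, where sampling alone gave 0.483%. A common spread beyond sampling of 1.1% was estimated from genes of at least 1000 estimated reads and used for every gene. Between 1 and 5 TPM the median CV of estimated reads was 9.59%, where sampling alone gave 8.61%. The common spread may thus be too small for genes with few reads, and calls among them are less certain. Among 502 genes with at least 10000 estimated reads, the median chi-square between libraries was 2.41, 3.69 and 3.67 times that of sampling noise, and the libraries were kept as 3 samples, which does not settle whether they were prepared separately. Limma's test for excess spread called 0 of 13475 genes (548 at an unadjusted p under 0.05, lowest adjusted p = 0.45), and it recovered 0% of genes given extra spread in simulated data. A read-based test added after the data were seen called 168 of 13988 genes. Its named genes were chosen after their values were seen: RGPD6, a RANBP2-like gene, was listed at 7.32 ± 3.54 TPM, its relative RGPD5 at 22.5 ± 5.34 TPM, and the splicing factor genes U2AF1 and U2AF1L5, near copies on chromosome 21, at 241 ± 36.5 TPM and 384 ± 42.4 TPM. FGF23 (chromosome 12, 4368227 to 4379728, hg38), which encodes a phosphate-regulating hormone, was listed at 62.8, 46.7 and 54.1 TPM in replicates 1, 2 and 3, about 3652 estimated reads per library (read-based test, adjusted p = 1.44e-21).

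**Figure D3:**
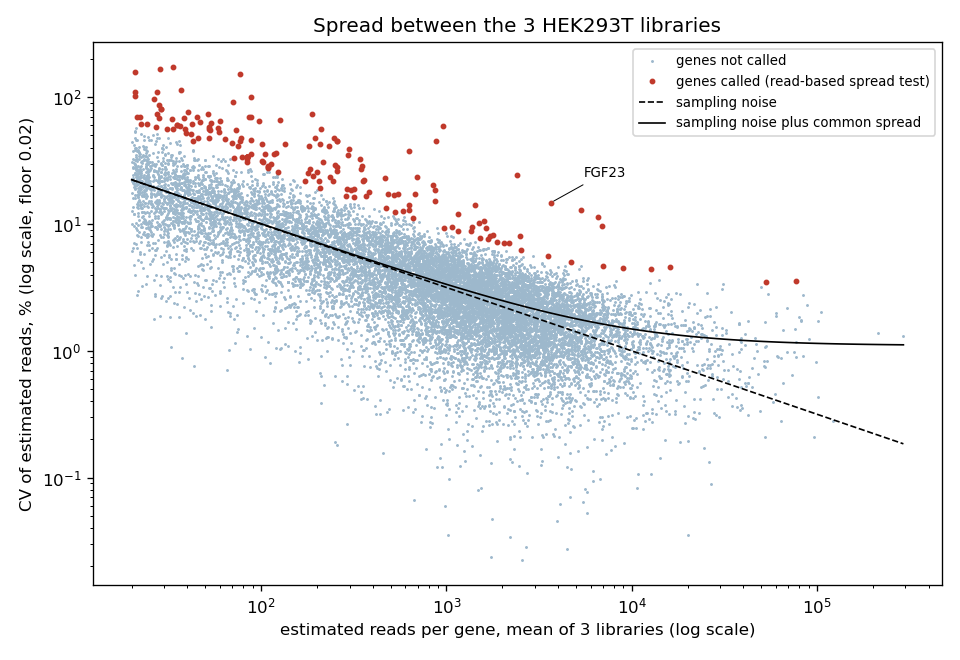
CV of estimated reads between the 3 HEK293T libraries (percent, log scale) against the mean number of estimated reads per gene (log scale), 1 point per gene with at least 20 reads. The dashed line is sampling noise, the solid line adds the common spread of 1.1%, and the 168 genes called by the read-based test are red.

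The most abundant transcript of a gene was mostly the same in the 3 libraries. Of 10081 genes with at least 5 TPM and more than 1 transcript, 8799 (87.3%) had the same main transcript throughout, and it held a median of 58.2% of the gene's TPM. In 36.8% of those genes the main transcript held under 50%. EEF1A1 drew 69.1% ± 0.443 of its TPM from 1 protein-coding transcript, RPL41 94.4% ± 0.093, RPS2 73.2% ± 0.648, RPL39 99.7% ± 0.0429 and RPL37A 75.4% ± 0.0717 (SD, n = 3). Among genes whose main transcript changed between libraries, the most abundant were the splicing factor gene HNRNPA1, where the leading transcript of replicate 1 held 31.9% ± 0.933, and BEX3, PLS3, COX5A and NDUFC2, where it held 42.9% ± 3.74, 49.6% ± 1.93, 41.8% ± 1.83 and 47.6% ± 1.24. The main transcript was annotated as protein-coding in 89.9% of the 8799 genes, as a target of nonsense-mediated decay in 2.35%, and as a retained intron in 2.18%. No test was made of these shares, and transcripts that differ by little sequence are separated by the quantification model alone.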

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

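Added after the data were seen were edgeR on estimated reads, the read-based spread test and the protein-coding background, and the other settings were fixed in advance. The count of genes above 1 TPM ranged from 12720 to 13033 over the alternatives that kept that level, and 11879 genes lay above 2 TPM and 13737 above 0.5 TPM. No gene called above by the planned test was called below, or the reverse, under any alternative except another level: 18 genes below 1 TPM were above 0.5 TPM and 180 genes above 1 TPM were below 2 TPM. Of the 12856 genes above 1 TPM, 12839 were also above by edgeR. TMM and median-of-ratios scaling moved no listed count by more than 1.5 times. Without replicate 1, 2 or 3 the genes below 1 TPM numbered 5359 to 5631, with 2 libraries left for each test, and the number of differing pairs stayed at 37 (38 with a pseudocount of 1). Among the listed genes still tested 14, 8 and 7 lost their call without replicate 1, 2 and 3, and genes left at 0 in both remaining libraries were not tested. Rescaling without mitochondrially encoded genes ended the calls of APOBEC3H (log2 -1.25, limma adjusted p = 0.0552) and CHRM3 (-0.52, 0.0749). No paired analysis was possible because the series holds 1 group. Pairs in CPM without length scaling and the edgeR dispersion were planned for counts per library and were not run on estimated reads. The mitochondrial list has no value when its genes are removed. Depth limits calls near 1 TPM, where a gene rests on about 47.4 reads per 2000 bases.

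At 0.5 TPM, members above the level numbered 6 for nucleic acid sensing, 5 for cytidine deaminases and 1 for adrenal markers, and members below it 3 for virus entry receptors, 4 for G protein-coupled receptors, 1 for epithelium and 3 for blood cells. At 2 TPM, members above the level numbered 3 for channels, 2 for epithelium and 1 for blood cells, and members below it 2 for mismatch repair, 10 for nucleic acid sensing, 5 for cytidine deaminases, 11 for channels and 5 for immediate early genes. These follow from the level itself. Among listed genes called at either level, these changed sign against 0.5 TPM (log2 against the level): APOBEC3D 0.68, AQP1 0.0169, BST2 0.38, CACNA1G 0.81, CHGA 0.95, CHRM3 0.36, CLDN4 0.16, CLDN7 0.86, COL3A1 0.86, CTGF 0.81, DHX58 0.73, EGR1 0.53, FOSB 0.82, HIST2H2BE 0.85, IFI44L 0.88 and TMEM173 0.91. Against 2 TPM these were among those that did: APOBEC3G -0.88, CACNA1A -0.24, DDX58 -0.88, DPP4 -0.38, EPCAM -0.25, GAP43 -0.19, HIST1H1E -0.29, HIST1H3B -0.11, LUM -0.35, MLH3 -0.77, MX2 -0.00943, P2RY2 -0.38, PAX2 -0.35 and SCN4A -0.64. Testing only genes of at least 0.1 TPM, which removes low genes by construction, left 3493 genes below 1 TPM, and members below of 3 for nucleic acid sensing, 4 for interferon-stimulated genes, 0 for RNA modification, 5 for G protein-coupled receptors, 1 for replication-dependent histones, 2 for kidney, 3 for neurons, 1 for epithelium, 2 for mesenchyme and 2 for endothelium. It gave 4 for immediate early genes, as did edgeR on estimated reads, where FOS and EGR1 passed (the cause was not tested).

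Leaving out 1 replicate each gave members below 1 TPM of 0 to 1 for mismatch repair, 1 to 3 for immediate early genes, 0 to 2 for epithelium and 3 to 5 for blood cells. The median CV between libraries was 3.71% over genes of at least 5 TPM and 6.62% over genes of at least 0.1 TPM. Without a replicate it was 3.63% to 3.74%, but the median of a CV over 2 libraries is lower by construction. That fall therefore shows no smaller spread. The median correlation was 0.984 to 0.986 without a replicate, 0.971 with a pseudocount of 0.01, 0.994 with a pseudocount of 1, 0.994 over genes of at least 5 TPM and 0.979 over genes of at least 0.1 TPM. Excess spread was called in 0 genes under each other setting of limma's test and in 168 by the read-based test. Against coding genes 18 lists rather than 14 differed from the rest, with nucleic acid sensing, channels, kidney, blood and endothelium gained and virus entry receptors lost.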

Other observations

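Gene families were chosen and tested after the data were seen, as were the tests of the spread between libraries, while the tests of shared sequence and of the mitochondrial ribosomal RNA were written before their results were seen. Homeobox genes of the HOX clusters, which set position along the body axis, were expressed across all 4 clusters: 35 of 39 lay above 1 TPM (Fisher's exact test against coding genes, adjusted p = 0.000279 over 10 families, 4 of them the single clusters). By cluster, 11 of 11 HOXA genes (adjusted p = 0.0182), 9 of 10 HOXB genes (0.168), 8 of 9 HOXC genes (0.239) and 7 of 9 HOXD genes (0.552) lay above, so only HOXA passed on its own. HOXB9 stood at 85.7 ± 1.16 TPM, HOXB6 at 69.8 ± 4.19 TPM, HOXA9 at 69.5 ± 1.81 TPM and HOXD13 at 67.9 ± 1.09 TPM. HOXC12, HOXD1 and HOXD12 lay below, at 0.432 ± 0.0296 TPM, 0.576 ± 0.0803 TPM and 0.265 ± 0.0369 TPM, and HOXB1 was listed at 0.

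Other families were mostly low or mixed. Of 55 keratin genes, 4 lay above 1 TPM and 40 were listed at 0 (adjusted p = 1.76e-16), and of 385 odorant receptor genes 2 lay above (adjusted p = 1.73e-156). Of 13 GAGE cancer-testis genes 0 lay above 1 TPM (adjusted p = 1.37e-05), whereas 5 of 12 MAGEA genes did (adjusted p = 0.292), among them MAGEA3 at 21.8 ± 0.432 TPM and MAGEA6 at 21.8 ± 0.754 TPM, which are near copies. Among 19 SOX genes, 11 lay above 1 TPM (adjusted p = 0.815), with SOX12 at 51.2 ± 0.811 TPM.

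The spread between the 3 libraries was small. Among genes of at least 10000 estimated reads the lowest of the 3 library pairs had a median chi-square 2.41 times that of sampling, and 1.99 times in the 135 such genes that share under 1% of their words. Repeated sequencing of 1 library could also add spread beyond sampling, from runs, read assignment, the estimated depths or the single set of effective lengths. No library known to be sequenced repeatedly was there to compare, so repeated sequencing cannot be told apart from separate libraries. Separate libraries from a shared culture or RNA could also give the common spread of 1.1%, and this cannot be told apart from separate cultures, since no libraries from cultures known to be separate were there to compare. No biological explanation was tested, since the design holds 1 group.

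Genes that varied beyond the common spread may mostly reflect how reads are divided between near-identical sequences. Of the 150 called genes with sequence (89.3% of 168), 120 (80%) share at least 50% of their 31-base words with another gene, against 53 of 750 uncalled genes matched on reads (7.07%, Fisher's exact p = 4.14e-77). Called genes are not independent, so this p only describes the set. Near copies such as RGPD5 and RGPD6 were called together, and some of the 168 symbols had identical estimated reads. Summed over a pair, estimated reads had a CV of 0.515% for U2AF1 and U2AF1L5 (13.1% and 11.3% singly, 0.918% from sampling). For RGPD5 and RGPD6 it was 1.11% (24.8% and 58.9%, 1.73% from sampling). In both pairs the split varied, and the sum stayed within sampling. The sum lay close to sampling for SULT1A3 with SULT1A4 (3.56% against 3.62%) and for EIF3C with EIF3CL (0.683% against 0.564%). Sums further above sampling were SMN1 with SMN2 (2.94% against 1.56%) and ERCC5 with BIVM-ERCC5 (6.15% against 2.59%). These CVs were not scaled for the estimated depths, and a CV over 3 libraries is imprecise. Sums close to sampling therefore cannot be placed on either side of it. Of the other 30 called genes with sequence, 21 share at least 1% and under 50% of their words, among them MAFF (3.07%, adjusted p = 3.27e-13), the pseudogene SINHCAFP3 (3.01%, 2.72e-10) and CDH8 (1.84%, 2.78e-05), and for these the share decides nothing. The last 9 share under 1%, so same-strand sequence shared with another matched gene is unlikely to account for their spread: FGF23 (0.268% of its words, adjusted p = 1.44e-21), and ASPM, TSPO, JUND, TSNARE1, ZNF711, PPP2R5A, NISCH and EPHA2 with 0% to 0.770% and adjusted p from 0.00486 to 0.0482. Overlap with antisense genes and with transcripts not matched to the annotation was not measured, so reads shared with those are not excluded. All but FGF23 lie nearer the threshold of 0.05, and some of them may be false calls. The cause of the spread of these 9 genes stays open, and no biological explanation was tested.

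MTRNR2L12, a nuclear gene derived from the mitochondrial 16S ribosomal RNA (chromosome 3, 96617188 to 96618236, hg38), was listed at 2645 ± 92.6 TPM. Reads of the 16S RNA itself, MT-RNR2, which was not analysed here, may be assigned to it: 33.6% of its 31-base words occur in MT-RNR2, and over the 13 MTRNR2L genes TPM rose with that percent (Spearman's rho 0.751, permutation p = 0.00388, across genes that are not independent). MTRNR2L8, with 21.8% of its words in MT-RNR2, was listed at 344 ± 15.4 TPM, and MTRNR2L13, with 0%, at 0.0676 ± 0.0336 TPM. Other members departed from the trend: MTRNR2L4 (0.289%) stood at 23.9 ± 0.903 TPM and MTRNR2L11 (1.05%) at 34.6 ± 1.38 TPM. In the other direction, MTRNR2L2 (7.02%, which is 4 of only 57 words) was at 2.20 TPM on average and MTRNR2L3 (1.26%) at 0.0107 TPM. With the number of shared words instead of the percent, Spearman's rho was 0.828. Transcription of MTRNR2L12 itself was not tested and stays open.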
